A study of Mus musculus with 12 samples.

How the data were processed

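RNA of mouse haematopoietic progenitor cells was measured in 12 libraries, 3 each of untransduced, vector, Evi1-WT and Evi1-S436A cells at 48 h. Per the labels' protocols, 200 ng of RNA went into the QuantSeq 3′ kit with 14 cycles, and reads of 75 bp were sequenced. The method counts tags near the 3′ end of polyadenylated transcripts. Per the submitters' processing notes, the authors used DESeq2 and the GRCm38 genome. The aligner, the annotation and the versions are not given in the sources used here. The deposited table holds log2 values for 23766 Ensembl genes, from -2.25 to 20.58, and their form resembles a regularized log transform, though no source used here states which transform was applied. In such values 1501 genes sit at a floor in all 12 libraries, within 0.01 of each other, and fold changes of low genes are shrunk. No counts were in the table, so the depth of each library is unknown, and tests that need counts were not run.

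The design written before the table was seen planned edgeR on counts, which was not run, or limma-trend on log2(value + 1) for normalized values. As the values were already on a log2 scale, limma-trend was run on them as deposited, with no pseudocount. Genes with a mean of at least 3.32, the log2 of 10, over the 12 libraries were kept, 11698 in all. The planned filter was on counts, and its form on this scale was chosen after the table was seen. All 12 libraries went into 1 fit of the 4 group means with no covariates, using limma 3.58.1 in R 4.3.3, and p-values were adjusted by Benjamini and Hochberg at a false discovery rate of 0.05. Errors of group means are SD over 3 libraries, and errors of fold changes are the SE of the moderated fit, with a median of 0.221. As all groups shared 1 estimate of the spread, this median is the same in every comparison. The median gene SD, however, ran from 0.164 with vector to 0.321 in untransduced cells. The SE may therefore be too small against untransduced cells and too large among the transduced groups.

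Gene symbols came from the Ensembl gene table, which matched 23371 of the 23766 identifiers and left 395 without a symbol. Positions are from the GRCm38 annotation. Before the data were examined, 30 lists of genes were written down. Of these, 27 had at least 5 members past the filter and were tested by camera with a preset correlation between genes of 0.01, with an estimated correlation and with fry beside it. That camera used the mean-variance trend was chosen after the values were seen. The lists of B cell genes (3 members past the filter), T and NK cell genes (4) and stromal and endothelial genes (3) were too small for it. With an estimated correlation, the lists called fell from 12 to 5, from 14 to 1 and from 9 to 1 in the first 3 comparisons, and fry called 13, 2 and 3.

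Named genes follow a rule fixed beforehand. It takes the 12 higher and 12 lower called genes with the largest change and with no overlap between groups, or the 10 lowest p where fewer than 5 passed, up to 4 members of each discussed list, and 10 fixed genes. Of these 8 are given (Mecom, Ctbp1, Dnmt3a, Gata2, Spi1, Cebpa, Meis1 and Hoxa9) and 2 are not reported here. Ctss and Gpnmb in Evi1-WT, named to complete a count, and the contrasting genes Csf1r and Cd14 were added after their values were seen. So were Hba-a1 and Apoe in the comparison of the 2 Evi1 forms.

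The comparisons were vector against untransduced, each Evi1 form against vector, and Evi1-S436A against Evi1-WT. The 2 Evi1 forms were also compared with untransduced cells, as the alternative control. Calls shared by the 2 forms were set beside the product of the numbers called over the number of genes, and beside 100 simulations of unchanged groups sharing the vector libraries. The scripts were tested on simulated data with 200 changed genes among 11698. For vector against untransduced they recovered 16% of log2 changes of 0.5, 74% of changes of 1 and 100% of changes of 2. For Evi1-WT against vector these were 6%, 74% and 100%, for Evi1-S436A against vector 2%, 70% and 100%, and for Evi1-S436A against Evi1-WT 4%, 74% and 100%. False calls made up 4.6%, 3.4%, 5.6% and 6.7% of the calls in these 4 comparisons. All groups were simulated with 1 common spread per gene, so these shares differ between the comparisons only by the random draw. The unlike spreads of the real groups were not simulated, so the shares need not hold for the real comparisons.

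Alternatives planned before the data were examined were no filter, a stricter filter in at least 6 libraries, a fit of the 2 groups alone, the replicate number as a block, a test against a log2 fold of 0.5, the untransduced control, an estimated correlation and leaving out each library in turn. Chosen after seeing the data were quantile normalization, median centring, array weights, a robust prior, no mean-variance trend in limma or camera and a fit without the untransduced libraries.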

Results

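RNA was measured in haematopoietic progenitor cells of C57BL/6 mice, collected 48 h after lentiviral transduction with wild-type Evi1 (Evi1-WT), with the mutant Evi1-S436A or with an empty vector, beside untransduced cells. EVI1 is a zinc-finger transcription factor of stem cells and myeloid leukaemia, encoded at the Mecom locus, and S436A exchanges a serine for an alanine, which cannot be phosphorylated. The study asked what phosphorylation at that serine does to EVI1. There were 3 libraries in each of the 4 groups, made by a 3′ tag method, and 11698 genes with a mean log2 value of at least 3.32 were tested. The deposited table holds log2 values and no counts, so the depth of each library is unknown. Nothing in the labels says that the replicates are separate cultures or animals, so the p-values measure only the spread between these samples. The labels give libraries with the same replicate number a shared code across the 4 groups and do not say what it stands for. Fold changes below are differences of group means on the log2 scale with the standard error (SE) of the limma fit, from 3 libraries per group, and adjusted p-values are from limma unless another test is named.

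The untransduced libraries stood apart from all transduced ones. Component 1 of a principal component analysis held 37.8% of the variance and placed the untransduced libraries between -44.1 and -41.1 and the other 9 libraries between 11.1 and 17. Component 2 held 16.8% and placed untransduced replicate 3 at -34.3, against 15.1 and 22.3 for replicates 1 and 2 of that group. The untransduced libraries also differed most among themselves, with a median gene SD of 0.321, against 0.164 in the vector group, 0.197 in Evi1-WT and 0.198 in Evi1-S436A (n = 3 libraries each). Correlations within the untransduced group ran from 0.949 to 0.976, and those within the vector group from 0.989 to 0.991.

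**Figure D1:**
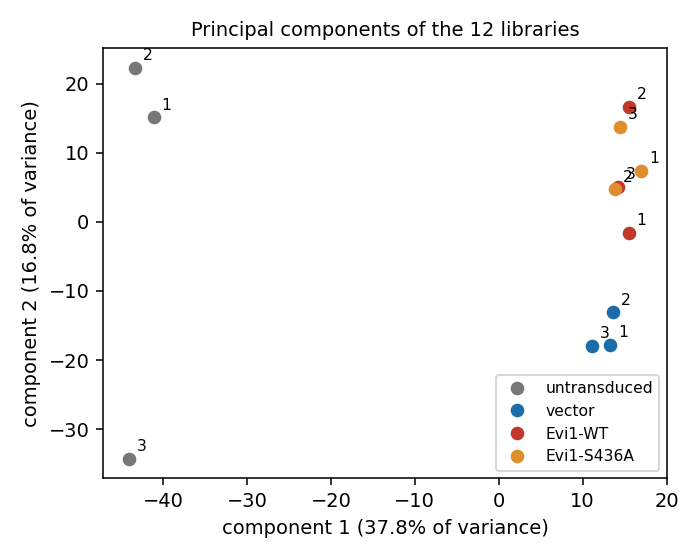
Principal components 1 and 2 of the 12 libraries, from the tested genes. Each point is 1 library, coloured by group and numbered by replicate.

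Mecom (ENSMUSG00000027684, GRCm38 chromosome 3, 29951296 to 30548008) was low in all groups. Its mean log2 value was 5.24 ± 0.52 (SD, n = 3) in untransduced cells, 4.71 ± 0.13 with vector, 4.60 ± 0.27 with Evi1-WT and 4.61 ± 0.35 with Evi1-S436A. It passed in no comparison: the difference was -0.12 ± 0.27 (SE) for Evi1-WT against vector (limma adjusted p = 0.961) and -0.11 ± 0.27 for Evi1-S436A against vector (limma adjusted p = 0.930). A 3′ tag from the viral construct need not fall within the annotated Mecom gene, so these values check nothing about the labels or about the amount of EVI1.

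The comparison of vector with untransduced cells asked what transduction and its handling alone did. Metallothionein genes, which respond to metals and stress, rose most: Mt2 (ENSMUSG00000031762, GRCm38 chromosome 8, 94172664 to 94173568) went from 9.10 ± 0.18 to 14.11 ± 0.24 (SD, n = 3), a log2 difference of 5.01 ± 0.17 (SE, limma adjusted p = 7.49e-12), and Mt1 rose by 3.89 ± 0.16. All 15 hypoxia target genes rose, with a median log2 change of 1.75, among them the oxygen sensors Egln3 (2.93 ± 0.22) and Egln1 (2.35 ± 0.18) and the mitophagy gene Bnip3 (2.34 ± 0.15). Glycolysis genes rose in 12 of 16 cases and in 13 adjusted over the list alone, including Tpi1 (1.30 ± 0.15), Ldha (1.17 ± 0.14) and the glucose transporter gene Slc2a1 (1.43 ± 0.18). Of 29 interferon response genes, 28 fell, and 29 adjusted over the list alone, with a median of -1.59. Among them were the antiviral gene Rsad2 (ENSMUSG00000020641, GRCm38 chromosome 12, 26442746 to 26456452), which fell by 3.65 ± 0.24, Oasl2, which fell by 2.63 ± 0.19, and Irf7, a transcription factor of the interferon response, which fell by 2.53 ± 0.27. Inflammatory cytokine genes under NF-kB control fell in 11 of 21 cases, and in 14 adjusted over the list alone. Il1b, which encodes interleukin 1 beta, fell by 3.55 ± 0.34, and the chemokine gene Ccl3 fell by 1.98 ± 0.14. Of 25 genes of G2 and M phase, 24 rose, and 25 adjusted over the list alone, with a median of 1.49 and with the centromere gene Cenpf at 2.03 ± 0.20 and Kif23 at 1.64 ± 0.16. Cholesterol synthesis genes rose in 12 of 21 cases, and in 14 adjusted over the list alone, with Fdps at 1.30 ± 0.17 and Hmgcs1 at 1.14 ± 0.16. Targets of p53 fell in 7 of 20 cases, and in 8 adjusted over the list alone, with Mdm2 at -1.13 ± 0.17. The homeobox gene Hoxa9 rose by 1.65 ± 0.27 (limma adjusted p = 0.00045), while Gata2 (0.15 ± 0.20), Meis1 (0.14 ± 0.25), Spi1 (-0.26 ± 0.17), Cebpa (0.47 ± 0.16), Ctbp1 (0.36 ± 0.15) and Dnmt3a (-0.05 ± 0.17) did not pass.

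Markers of cell types moved in both directions between vector and untransduced cells. The azurophil granule genes Prtn3 (2.27 ± 0.17), Ctsg (1.78 ± 0.15), Mpo (2.10 ± 0.29) and Elane (2.39 ± 0.45) rose with 2 other members of the 20 neutrophil genes (7 rose and 1 fell adjusted over the list alone), while Chil3 fell by 3.62 ± 0.73, with an SD of 2.47 in the untransduced group (n = 3), and lost its call without the filter on low values (limma adjusted p = 0.0507). The neutrophil list had a median of 0.41 (camera adjusted p = 0.0170, and adjusted p = 0.479 with an estimated correlation), and the call was lost without untransduced replicate 3, where the direction turned (camera adjusted p = 0.936). Of 13 megakaryocyte genes 5 fell, both over all genes and adjusted over the list alone, including Itgb3 (-1.09 ± 0.17) and Gfi1b (-1.42 ± 0.28), and Gp1bb rose (camera adjusted p = 0.0147, and adjusted p = 0.291 with an estimated correlation). Of 12 mast cell and basophil genes 5 fell, both over all genes and adjusted over the list alone, including Il1rl1 (-1.14 ± 0.21) and Fcer1a (-1.04 ± 0.25; camera adjusted p = 0.0262, and adjusted p = 0.468 with an estimated correlation). Both lists lost the call without untransduced replicate 1 (camera adjusted p = 0.0516 and 0.284). The monocyte marker F13a1 rose by 3.37 ± 0.28, but the monocyte and macrophage list held 3 higher and 3 lower genes and was not called (camera adjusted p = 0.864). In the lists too small for the set test, Thy1 rose by 1.95 ± 0.19, Nkg7 rose by 0.56 ± 0.19, Vpreb1 fell by 2.08 ± 0.33, Pecam1 fell by 1.30 ± 0.18 and Kdr rose by 0.95 ± 0.20.

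In all, limma called 1261 genes higher and 1143 lower in vector than in untransduced cells, 2404 of 11698, and 870 of these changed at least 2-fold. All 3 libraries of 1 group lay above all 3 of the other for 33.7% of genes, where chance gives 10%. By camera with its preset correlation, 12 of 27 lists were called: hypoxia (adjusted p = 9.75e-17), interferon response (2.32e-25), G2 and M phase (1.96e-22), glycolysis (2.53e-09), NF-kB and cytokine (2.42e-07), cholesterol synthesis (3.27e-07), p53 target (0.00230), oxidative phosphorylation (0.00585) and cytosolic ribosomal protein genes (0.0265) beside the 3 cell type lists above. The hypoxia list kept its call (adjusted p = 0.00044 with an estimated correlation), as did glycolysis (adjusted p = 0.0239 with an estimated correlation), NF-kB (adjusted p = 0.0368 with an estimated correlation), p53 targets (adjusted p = 0.0382 with an estimated correlation) and interferon response (adjusted p = 0.0425 with an estimated correlation). The call was lost for G2 and M phase and for cholesterol synthesis (each adjusted p = 0.0753 with an estimated correlation). It was also lost for oxidative phosphorylation, where 6 of 35 genes rose over all genes and adjusted over the list alone (adjusted p = 0.291 with an estimated correlation). The ribosomal list, where 3 of 35 rose and 2 adjusted over the list alone, lost it too (adjusted p = 0.593 with an estimated correlation). The ribosomal call was further lost without untransduced replicate 2 (camera adjusted p = 0.0642), untransduced replicate 3 (0.0541) or vector replicate 1 (0.120) and after quantile normalization (0.0526). The other 15 lists did not pass, with medians from -0.50 to 0.38 and camera adjusted p from 0.0534 to 0.864. The count of genes was 1571 without vector replicate 1, 1529 without replicate 2 and 1567 without replicate 3, 1398 in a fit of the 2 groups alone and 421 against a log2 fold of 0.5. Gm26461 (3.36 ± 0.30) and Gm15283 (3.39 ± 0.25) also rose, but a small-RNA copy and an antisense transcript may take reads from related sequences, and their identity is uncertain.

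**Figure D2:**
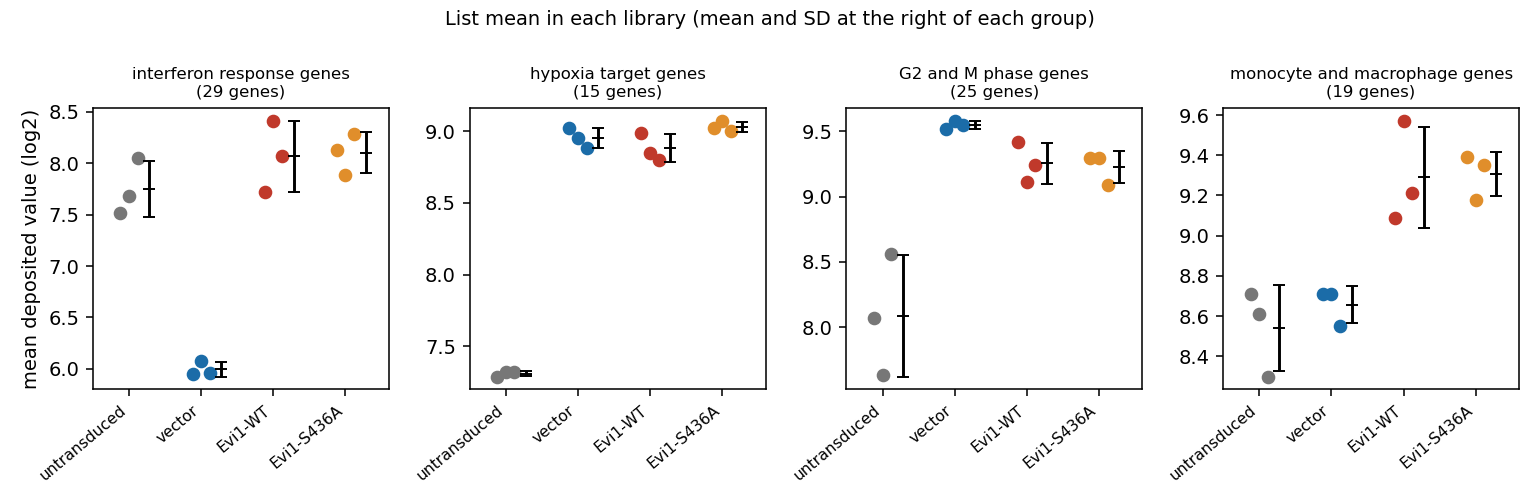
Mean log2 value of 4 gene lists in each of the 12 libraries, with the mean and SD of each group of 3 libraries.

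The comparison of Evi1-WT with vector asked what the Evi1 construct changed beside the empty vector. Each construct came in its own virus, so a difference between the viruses cannot be told apart from an effect of EVI1 with these samples. Interferon response genes were the largest group: 27 of 29 rose, and 29 adjusted over the list alone, with a median log2 change of 1.82. Among them were Ifit3 (ENSMUSG00000074896, GRCm38 chromosome 19, 34583531 to 34588731), from 4.44 ± 0.28 to 7.98 ± 0.50 (SD, n = 3; 3.54 ± 0.29 SE, limma adjusted p = 1.13e-06), Rsad2 (3.28 ± 0.24), Ifi27l2a (3.28 ± 0.20) and Oasl2 (2.89 ± 0.19). The list passed camera (adjusted p = 2.09e-79) and was the only one to keep its call (adjusted p = 0.00638 with an estimated correlation). Against untransduced cells the same list was not called in Evi1-WT (median 0.23, camera adjusted p = 0.0742), where 6 members were higher and 1 lower. The mean of the 29 genes was 7.75 ± 0.27 (SD, n = 3) in untransduced cells, 6.00 ± 0.07 with vector, 8.07 ± 0.35 with Evi1-WT and 8.10 ± 0.20 with Evi1-S436A, so the vector group was the low one. Members of the Ifit, Ly6, Ifi and Phf11 families and the globins share sequence with their neighbours, so reads may be split among paralogs and single members are uncertain.

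Outside that list, the largest rises included the alpha-globin gene Hba-a1 (ENSMUSG00000069919, GRCm38 chromosome 11, 32283511 to 32284465; 4.36 ± 0.44), the surface antigen gene Ly6i (3.92 ± 0.46), the Ifit family gene Ifit1bl1 (3.41 ± 0.26), the lipoprotein gene Apoe (3.23 ± 0.30) and Cited1, which encodes a transcriptional co-regulator (3.20 ± 0.23). Ly6a, which encodes the stem cell antigen Sca-1 and also responds to interferon, rose from 10.28 ± 0.11 to 12.96 ± 0.51 (SD, n = 3; limma adjusted p = 2.45e-05) and was the only 1 of 25 stem and early progenitor genes to rise, both over all genes and adjusted over the list alone. Of 19 monocyte and macrophage genes 6 rose, and 8 adjusted over the list alone: Apoe, the lysozyme gene Lyz2 (1.65 ± 0.25), the osteopontin gene Spp1 (2.13 ± 0.33), Cd68 (1.06 ± 0.19), Ctss and Gpnmb. The receptor gene Csf1r (0.12 ± 0.19) and Cd14 (0.07 ± 0.33) did not pass. The list passed camera (adjusted p = 5.38e-07), but not otherwise (adjusted p = 0.218 with an estimated correlation). Of 14 erythroid genes Hba-a1 and Hbb-bs (2.70 ± 0.32) rose, and 4 adjusted over the list alone (camera adjusted p = 0.000646, and adjusted p = 0.256 with an estimated correlation). Of 20 neutrophil genes 4 fell, and 7 adjusted over the list alone: Mpo (-1.20 ± 0.29), Ctsg (-0.67 ± 0.15), Cebpe (-0.96 ± 0.23) and Fcnb (-1.14 ± 0.27; camera adjusted p = 5.38e-07, and adjusted p = 0.281 with an estimated correlation). Mpo lost its call without vector replicate 1 (limma adjusted p = 0.0969), vector replicate 2 (0.125), vector replicate 3 (0.189), Evi1-WT replicate 2 (0.244) or Evi1-WT replicate 3 (0.157), with a robust prior (0.0673) and without the mean-variance trend (0.0782). Fcnb lost it without vector replicate 1 (limma adjusted p = 0.0842), vector replicate 2 (0.182), vector replicate 3 (0.173), Evi1-WT replicate 2 (0.212) or Evi1-WT replicate 3 (0.219). Cebpe lost it without vector replicate 1 (limma adjusted p = 0.0969), vector replicate 2 (0.179), vector replicate 3 (0.161), Evi1-WT replicate 1 (0.0560), Evi1-WT replicate 2 (0.257) or Evi1-WT replicate 3 (0.131). Fcnb and Cebpe both lost it without the mean-variance trend (0.0761 and 0.0737). Of 21 NF-kB and cytokine genes Ccl5 (1.06 ± 0.19) and Traf1 (1.05 ± 0.24) rose, and 4 adjusted over the list alone (camera adjusted p = 0.000672, and adjusted p = 0.224 with an estimated correlation). The direction turned with untransduced cells as the control for the NF-kB list, which was called lower (median -0.43, 2 higher and 7 lower, camera adjusted p = 0.00171). The neutrophil list (-0.23, 4 higher and 2 lower, camera adjusted p = 0.927) and the erythroid list (0.29, 0.0722) then lost the call, and the monocyte list kept it (0.31, 0.00097). With an estimated correlation neither the NF-kB nor the monocyte list passed against untransduced cells. In the lists too small for the set test, the receptor gene Kdr rose by 1.23 ± 0.20 and Nkg7 fell by 1.00 ± 0.19. Nkg7 lost its call without vector replicate 3 (limma adjusted p = 0.0754) or Evi1-WT replicate 3 (0.0676). The stem cell factors Gata2 (-0.55 ± 0.20), Meis1 (0.07 ± 0.25) and Hoxa9 (-0.06 ± 0.27), the partners Dnmt3a (0.28 ± 0.17) and Ctbp1 (-0.21 ± 0.15), Spi1 (0.16 ± 0.17) and Cebpa (-0.55 ± 0.16) did not pass.

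In 8 other lists that camera called in Evi1-WT against vector, no member passed over all genes. These were G2 and M phase (median -0.29, camera adjusted p = 8.77e-06, adjusted p = 0.380 with an estimated correlation), S phase (-0.20, 0.00210, adjusted p = 0.449 with an estimated correlation) and eosinophil genes (-0.71, 0.00440, adjusted p = 0.338 with an estimated correlation), and the next 5. Immediate early genes (0.19, camera adjusted p = 0.0103, adjusted p = 0.296 with an estimated correlation) lost the call without vector replicate 3 (camera adjusted p = 0.0878) or Evi1-WT replicate 3 (0.0800). Cholesterol synthesis genes (-0.13, camera adjusted p = 0.0140, adjusted p = 0.372 with an estimated correlation) lost it without vector replicate 2 (0.0611), Evi1-WT replicate 1 (0.0526) or Evi1-WT replicate 3 (0.110) and after quantile normalization (0.0506). Oxidative phosphorylation genes (-0.13, camera adjusted p = 0.0189, adjusted p = 0.372 with an estimated correlation) lost it without vector replicate 3 (0.128), Evi1-WT replicate 2 (0.222) or Evi1-WT replicate 3 (0.0524) and after quantile normalization (0.143). Ribosomal protein genes (-0.16, camera adjusted p = 0.000950, adjusted p = 0.403 with an estimated correlation) lost it without Evi1-WT replicate 2 (0.346) and after quantile normalization (0.0856). Mitochondrially encoded genes (-0.25, camera adjusted p = 0.0103, adjusted p = 0.372 with an estimated correlation) lost it without Evi1-WT replicate 2 (0.133) and after quantile normalization (0.143). Of 12 mast cell genes 1 fell, and 3 adjusted over the list alone (-0.44, camera adjusted p = 0.0119, adjusted p = 0.372 with an estimated correlation), and the call was lost without Evi1-WT replicate 2 (0.0638) or Evi1-WT replicate 3 (0.0524). Adjusted over the list alone, 1 eosinophil gene and 1 immediate early gene passed, and none in the others. The remaining 13 lists did not pass (medians from -0.24 to 0.13, camera adjusted p from 0.112 to 0.574). Against untransduced cells the direction turned for G2 and M phase, with 22 of 25 genes higher (median 1.22, camera adjusted p = 5.04e-17), and for cholesterol synthesis, with 9 of 21 higher (0.53, 0.00025). The call was lost for S phase (0.10, camera adjusted p = 0.873), immediate early (0.28, 0.199), oxidative phosphorylation (0.14, 0.142) and ribosomal protein genes (0.03, 0.842). Mast cell (-0.80, camera adjusted p = 0.000445), eosinophil (-0.78, 0.0131) and mitochondrially encoded genes (-0.57, 0.000861) were lower against both controls. With an estimated correlation none of the 14 lists passed against untransduced cells (lowest adjusted p = 0.182).

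Limma called 189 genes higher and 22 lower in Evi1-WT than in vector, 211 of 11698, of which 162 changed at least 2-fold. The groups did not overlap for 21% of genes, where chance gives 10%. All 12 higher genes named by the fixed rule, from Hba-a1 to Gbp2 (3.05 ± 0.26), kept their call in every setting with vector as the control. With untransduced cells as the control 10 of them did, and Ifit1 (0.50 ± 0.36, limma adjusted p = 0.369) and Rsad2 (-0.37 ± 0.24, limma adjusted p = 0.295) did not. Of the 12 lower genes only the small-RNA copy Gm26461 (-2.08 ± 0.30), whose identity is uncertain, kept its call in every setting with vector as the control. With untransduced cells as the control 5 lower genes kept the call. Gm26461 (1.28 ± 0.30, limma adjusted p = 0.00725) and Mpo (0.90 ± 0.29, limma adjusted p = 0.0368) were then higher, and Nkg7 (-0.44 ± 0.19) and Cebpe (-0.33 ± 0.23) did not pass. With vector as the control the 11 lower genes other than Gm26461 lost the call against a log2 fold of 0.5, among them Mpo (limma adjusted p = 0.936) and Nkg7 (0.769). Without the filter on low values 10 of them lost it, among them Mpo (limma adjusted p = 0.373), Fcnb (0.351), Cebpe (0.282) and Nkg7 (0.0866). The count of 211 was 132 without vector replicate 2, 123 without vector replicate 3, 106 without Evi1-WT replicate 2 and 131 without Evi1-WT replicate 3. It was 91 without the filter on low values, 63 against a log2 fold of 0.5, 600 in a fit of the 2 groups alone, 585 with array weights, 583 without the untransduced libraries in the fit and 2198 with untransduced cells as the control. Lower genes made up more of the larger counts, with 160 of the 600, 159 of the 585, 144 of the 583 and 939 of the 2198, against 22 of the 211.

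The comparison of Evi1-S436A with vector asked the same of the mutant. Interferon response genes rose again, 28 of 29 and 29 adjusted over the list alone, with a median log2 change of 2.01 (camera adjusted p = 2.37e-71, and adjusted p = 0.00922 with an estimated correlation), with Ifit3 at 3.68 ± 0.29, Rsad2 at 3.59 ± 0.24, Oasl2 at 3.07 ± 0.19 and Rtp4 at 2.80 ± 0.21. Against untransduced cells their median was 0.36, with 4 members higher (camera adjusted p = 0.0261, and adjusted p = 0.632 with an estimated correlation). Hba-a1 rose from 5.01 ± 0.05 to 9.28 ± 0.61 (SD, n = 3; 4.27 ± 0.44 SE, limma adjusted p = 1.45e-05), Ly6i by 3.92 ± 0.46, Apoe (ENSMUSG00000002985, GRCm38 chromosome 7, 19696109 to 19699188) by 3.30 ± 0.30, Cited1 by 3.19 ± 0.23 and Ly6a by 2.52 ± 0.29. Of 19 monocyte and macrophage genes 6 rose, and 10 adjusted over the list alone, with Lyz2 at 1.86 ± 0.25 and Gpnmb at 1.08 ± 0.19 (camera adjusted p = 1.89e-07, and adjusted p = 0.185 with an estimated correlation). Of 14 erythroid genes 3 rose, Hba-a1, Hba-a2 and Hbb-bs (3.09 ± 0.32), and the transferrin receptor gene Tfrc fell by 0.67 ± 0.15, while 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 5.66e-05, and adjusted p = 0.202 with an estimated correlation). Of 20 neutrophil genes Ctsg (-0.83 ± 0.15) and Ms4a3 (-0.89 ± 0.22) fell, and 5 adjusted over the list alone (camera adjusted p = 3.66e-05, and adjusted p = 0.321 with an estimated correlation). Of 21 NF-kB and cytokine genes 3 rose, Ccl5 (0.99 ± 0.19), Tnfaip2 (0.94 ± 0.20) and Traf1 (1.05 ± 0.24), while 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00237, and adjusted p = 0.254 with an estimated correlation). Set against untransduced cells instead, the NF-kB list turned and was called lower (median -0.59, 2 higher and 6 lower, camera adjusted p = 0.00108). The neutrophil list then lost the call (-0.10, 4 higher and 1 lower, camera adjusted p = 0.691), and the monocyte (0.42, 0.000359) and erythroid lists (0.37, 0.0209) kept it. With an estimated correlation none of the NF-kB, monocyte and erythroid lists passed against untransduced cells. In the lists too small for the set test, the vascular receptor gene Kdr rose by 1.40 ± 0.20 and Nkg7 fell by 0.98 ± 0.19. Nkg7 lost its call without vector replicate 3 (limma adjusted p = 0.0793), Evi1-S436A replicate 1 (0.0670) or Evi1-S436A replicate 3 (0.0698). It also lost it without the filter on low values (0.0862), against a log2 fold of 0.5 (0.876) and with untransduced cells as the control (0.140). The creatine synthesis gene Gatm fell by 1.25 ± 0.23 and the growth regulator gene Myc by 1.03 ± 0.22 (limma adjusted p = 0.0131). Myc lost its call without vector replicate 2 (0.0574), vector replicate 3 (0.106), Evi1-S436A replicate 1 (0.0617) or Evi1-S436A replicate 3 (0.0568). Against a log2 fold of 0.5 neither Myc (limma adjusted p = 0.913) nor Gatm (0.255) passed, and Gatm did not pass without the filter on low values (0.0564), where 10 of the 12 lower genes named by the fixed rule lost the call. With untransduced cells as the control Myc (-0.54 ± 0.22, limma adjusted p = 0.0898), Gatm (-0.05 ± 0.23, 0.910), Rsad2 (-0.06 ± 0.24, 0.887) and Oasl2 (0.45 ± 0.19, 0.115) did not pass. Gata2 (-0.79 ± 0.20, limma adjusted p = 0.0553), Dnmt3a (0.31 ± 0.17), Ctbp1 (-0.04 ± 0.15), Spi1 (0.43 ± 0.17), Cebpa (-0.23 ± 0.16), Meis1 (0.03 ± 0.25) and Hoxa9 (-0.11 ± 0.27) did not pass.

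No member passed over all genes in 4 other lists that camera called in Evi1-S436A against vector. They were G2 and M phase (median -0.27, camera adjusted p = 1.25e-05, adjusted p = 0.560 with an estimated correlation), S phase (-0.29, 3.59e-05, adjusted p = 0.560 with an estimated correlation), oxidative phosphorylation (-0.15, 0.00359, adjusted p = 0.321 with an estimated correlation) and ribosomal protein genes (-0.11, 0.0205, adjusted p = 0.695 with an estimated correlation). The ribosomal call was lost without vector replicate 1 (camera adjusted p = 0.183), Evi1-S436A replicate 1 (0.115) or Evi1-S436A replicate 3 (0.112). Adjusted over the list alone, 1 gene of G2 and M phase and 2 of oxidative phosphorylation passed. The other 18 lists did not pass (medians from -0.47 to 0.17, camera adjusted p from 0.0938 to 0.956). G2 and M phase turned when untransduced cells were the control, with 20 of 25 genes higher (median 1.18, camera adjusted p = 2.70e-16). The call was lost for S phase (-0.08, camera adjusted p = 0.586), oxidative phosphorylation (0.14, 0.353) and ribosomal protein genes (0.10, 0.482). With an estimated correlation none of the 9 lists passed against untransduced cells (lowest adjusted p = 0.202). Limma called 218 genes higher and 23 lower, 241 of 11698, of which 167 changed at least 2-fold, and the groups did not overlap for 25.2% of genes, where chance gives 10%. The count was 156 without vector replicate 2, 127 without vector replicate 3, 137 without Evi1-S436A replicate 1 and 122 without Evi1-S436A replicate 3. It was 75 without the filter on low values, 71 against a log2 fold of 0.5, 929 in a fit of the 2 groups alone, 812 with array weights, 744 without the untransduced libraries in the fit and 2202 with untransduced cells as the control. Lower genes made up more of the larger counts, with 323 of the 929, 264 of the 812, 230 of the 744 and 949 of the 2202, against 23 of the 241.

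The direct comparison of Evi1-S436A with Evi1-WT asked whether loss of the phosphorylated serine changed expression. No gene passed. The lowest p belonged to Xbp1, a transcription factor of the unfolded protein response (ENSMUSG00000020484, GRCm38 chromosome 11, 5520659 to 5525893), at 9.66 ± 0.15 with the mutant and 10.37 ± 0.21 with the wild type (SD, n = 3; -0.71 ± 0.15 SE). Myc followed (-0.97 ± 0.22), then Gatm (-0.89 ± 0.23), Tyw3 (0.80 ± 0.21) and the citrate cycle gene Idh3a (-0.78 ± 0.20), each with a limma adjusted p = 0.999. The interferon list had a median of 0.07 (camera adjusted p = 0.605), with Gbp2 at -0.64 ± 0.26 as the member with the lowest p. Without Evi1-WT replicate 2 the list was called higher in the mutant (camera adjusted p = 0.0058). The globin gene Hba-a1 (-0.09 ± 0.44), Apoe (0.07 ± 0.30), Gata2 (-0.24 ± 0.20), Spi1 (0.27 ± 0.17), Cebpa (0.33 ± 0.16), Meis1 (-0.04 ± 0.25), Hoxa9 (-0.04 ± 0.27) and the partners Dnmt3a (0.03 ± 0.17) and Ctbp1 (0.18 ± 0.15) did not pass either. All 27 lists stayed below the threshold, with medians from -0.11 to 0.32. The lowest camera adjusted p was 0.0543, for megakaryocyte genes (median 0.32, adjusted p = 0.819 with an estimated correlation), with Itgb3 at 0.46 ± 0.17 and Gp1bb at 0.61 ± 0.24. Fry called no list.

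Limma called 0 of 11698 genes between the 2 Evi1 forms, with 427 at an unadjusted p under 0.05, and the groups did not overlap for 11.2% of genes, where chance gives 10%. With 3 libraries against 3 the smallest exact p is 0.1, so an exact test of single genes could pass none. The median 95% confidence interval reached 0.467 to either side, and for 11098 genes (94.9%) it lay within a log2 difference of 1. These intervals are on the deposited scale. If fold changes of low genes are shrunk there, the intervals do not bound the unshrunken differences of such genes. In simulated data on the deposited scale, with 1 spread per gene for all groups, limma called 74% of log2 changes of 1 and 4% of changes of 0.5. Those data held 200 changed genes, which eases the adjusted threshold, so fewer isolated changes of that size would be called here. Myc, at -0.97 ± 0.22, had a limma adjusted p = 0.999. Without the filter on low values 2 genes were called lower, Cyp4x1os (-0.32) and Gm2308 (-0.09), both with mean values under 0 and chosen here after their values were seen. The count of lists was 4 in a fit of the 2 groups alone, 5 without Evi1-WT replicate 1, 4 without Evi1-WT replicate 3, and 1 without Evi1-WT replicate 2, without Evi1-S436A replicate 2, after quantile normalization or by camera without the mean-variance trend. The megakaryocyte list was called in a fit of the 2 groups alone (camera adjusted p = 0.0129), after quantile normalization (0.0363), and without Evi1-S436A replicate 2 (0.00096), Evi1-WT replicate 1 (0.0217) or Evi1-WT replicate 3 (0.0123).

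Both Evi1 forms were compared with the same 3 vector libraries. In both comparisons 156 genes were higher and 7 lower, 163 with the same direction, against 3.52 and 0.043 expected from the numbers called, and 0 with opposite direction. Among the 156 were Hba-a1, Apoe, Cited1 and Ly6a. Of the 289 genes called in at least 1 comparison, 288 had the same direction in both. The fold changes correlated at 0.817, where unchanged groups simulated against shared controls gave 0.50, and their covariance was 0.107 against 0.0269 simulated. The simulations gave 0.01 shared calls on average and 1 at most in 100. No gene was changed in them, so hardly any call could pass in either comparison. A shift of the vector group alone was not simulated. The simulated values therefore do not tell such a shift apart from agreement of the 2 forms. With Evi1-WT against vector and Evi1-S436A against untransduced cells, which share no library, 94 genes had the same and 16 the opposite direction, and with the controls exchanged 95 and 19. In the first pairing 84 were higher and 10 lower in both, against 20.2 and 1.78 expected from the numbers called. With the controls exchanged these were 90 and 5, against 23.5 and 1.85. The fold changes of these 2 pairings correlated at 0.186 and 0.155, and of the genes called in at least 1 comparison 1295 of 2303 and 1228 of 2325 had the same direction. The comparisons with untransduced cells called 2202 and 2198 genes and also hold the changes of transduction and handling. These correlations and shares therefore do not measure the agreement of the 2 forms alone. Part of the excess among the 163 genes may come from the shared controls: 86 of the 156 higher genes were also lower in vector than in untransduced cells. The count of 163 was 100 without vector replicate 3, 107 without Evi1-S436A replicate 3 and 100 without Evi1-WT replicate 2. It was 61 without the filter on low values, 59 against a log2 fold of 0.5 and 417 with array weights.

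**Figure D3:**
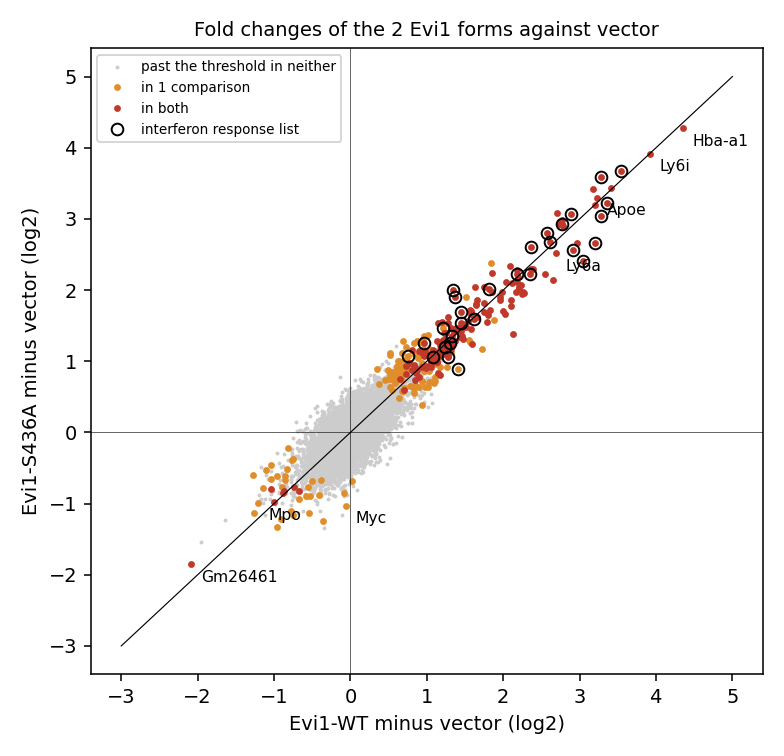
Log2 fold change of each tested gene in Evi1-WT and in Evi1-S436A against the same vector libraries. Colours mark genes past the threshold in neither, 1 or both comparisons, and open circles the interferon response list.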

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

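The added alternatives were chosen after the table was seen, and the planned ones before the data were examined. Alternatives that need counts (RLE and total library size normalization, DESeq2 and limma-voom) were not run. Genes changed in vector against untransduced cells (2404) moved to 1398 in a fit of the 2 groups alone and to 421 against a log2 fold of 0.5, and ranged from 1529 to 3211 with 1 library left out. Those in Evi1-WT against vector (211) moved to 91 without the filter, 600 in a fit of the 2 groups alone, 63 against a log2 fold of 0.5, 2198 with untransduced cells as the control (99 kept), 585 with array weights and 583 without the untransduced libraries, and ranged from 106 to 230 with 1 library left out. Those in Evi1-S436A against vector (241) moved to 75, 929, 71, 2202 (101 kept), 812 and 744 in the same settings, and ranged from 122 to 225. All 211 and all 241 genes stayed called in the fit without the untransduced libraries, whose spread is the widest. Between the 2 Evi1 forms the count stayed at 0 with every library left out and moved to 2 without the filter. Genes called against vector in both forms (163) moved to 61 without the filter, 59 against a log2 fold of 0.5, 417 with array weights and 94 or 95 with no shared control, and ranged from 100 to 165. With the replicate number as a block the counts were 2389, 224, 247, 0 and 171. Of 18 pairs of groups and numbers, 4 correlated above 0.1 (from -0.076 to 0.174). Their median was 0.039, against -0.011 for pairs of unlike number, and 7 of 12 libraries correlated best on average with their own number. The numbers were not taken as pairs, though a shared source is not excluded. The lists called (12, 14, 9 and 0) moved to 5, 1, 1 and 0 with an estimated correlation. With 1 library left out they ranged from 11 to 14, 10 to 15, 8 to 9 and 0 to 5. Between the 2 Evi1 forms they moved to 4 in a fit of the 2 groups alone and to 1 with the block (megakaryocyte genes, camera adjusted p = 0.0469), after quantile normalization and by camera without the trend. Dnmt3a in vector against untransduced cells turned to 0.11 and Hoxa9 in Evi1-WT against vector to 0.03 with array weights, neither of them called. The opposite also occurred. In 14 cases of 1 gene in 1 setting with the control kept, a named gene not called in the main fit was called. With 1 library left out, these genes that were not called in the main fit took both signs. In vector against untransduced cells Dnmt3a ranged from -0.22 to 0.12, Gata2 from -0.01 to 0.39 and Meis1 from -0.19 to 0.46. In Evi1-WT against vector Hoxa9 ranged from -0.21 to 0.12. In Evi1-S436A against vector Mecom ranged from -0.31 to 0.00, Ctbp1 from -0.12 to 0.07, Meis1 from -0.12 to 0.19 and Hoxa9 from -0.25 to 0.05. In Evi1-S436A against Evi1-WT Mecom ranged from -0.19 to 0.16, Dnmt3a from -0.04 to 0.07, Meis1 from -0.19 to 0.13 and Hoxa9 from -0.22 to 0.10. The camera adjusted p of the neutrophil list in vector against untransduced cells ranged from 0.000119 to 0.936. Of the called genes named by the rule, 23 of 25, 13 of 24 and 12 of 24 kept the call in every setting that kept the control group, and 10 and 9 of 24 when untransduced cells as the control were included. The cause of these moves was not tested.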

Other observations

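A group of genes, some of them named in the results, stood above both controls in both Evi1 forms. By a rule chosen after the values were seen, 75 genes were higher than vector and higher than untransduced cells with either form, and 2 were lower, the protease inhibitor genes Cst7 and Serpinb1a. The 75 held 4 interferon list members (Ifit2, Ifi27l2a, Ifit3 and Xaf1), where the 156 genes higher than vector alone held 26. That count covers the fixed list only. Members of the Ifit, Ifi and Phf11 families outside it were also among the 75, such as Ifit1bl1, Ifi206, Ifi207, Ifi208, Ifi209, Ifi211, Ifi213, Phf11b and Phf11d. Pdzk1ip1 had a mean of 7.62 ± 0.60 (SD, n = 3) in untransduced cells, 6.98 ± 0.41 with vector, 9.75 ± 0.38 with Evi1-WT and 9.96 ± 0.40 with Evi1-S436A. Cited1 had means of 2.92 ± 0.11, 3.07 ± 0.13, 6.27 ± 0.30 and 6.26 ± 0.33, and Rtl5, a retrotransposon-derived gene, 5.81 ± 0.62, 6.87 ± 0.86, 8.73 ± 0.37 and 9.11 ± 0.10. The receptor kinase gene Axl was higher than vector by 1.57 and 1.71 and than untransduced cells by 2.22 and 2.37 with Evi1-WT and Evi1-S436A. Serpinb1a was lower than vector by values of -0.89 and -0.85 and than untransduced cells by -0.71 and -0.67.

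The patterns below were picked after the results were seen, and of their tests the scaling, single-library, 2-group, split and regrouping ones were set before their results, the others after. Interferon genes higher in both Evi1 forms than in vector did not come from scaling between libraries, as the median stayed at 1.82 in Evi1-WT and 2.00 in Evi1-S436A after quantile normalization. A low vector group may account for much of it: against untransduced cells the median in Evi1-WT was 0.23, where it was 1.82 against vector, and which group left the usual level cannot be told apart with these samples. A larger share of monocytes or macrophages also stays open. The upper quartile of that list's folds was 1.06 and the lower quartile of the interferon folds 1.33, and after these were seen the rule, which had excluded this explanation, was tightened to ask for a gap beyond the spread of the folds. The medians lay further apart, at 0.36 (SD of the folds 0.97) against 1.82 in Evi1-WT and 0.55 (SD 0.91) against 2.01 in Evi1-S436A, and Csf1r (0.12 ± 0.19) and Cd14 (0.07 ± 0.33) did not pass in Evi1-WT. What keeps it open is the level with vector, with a median of 8.61 for the monocyte genes and 5.64 for the interferon genes, so that the same added transcripts move the monocyte genes less. How many transcripts of each list such cells would add was not measured. The interferon level can also move without the monocyte list. From untransduced to vector cells the interferon mean went from 7.75 to 6.00, and the monocyte mean from 8.54 to 8.66. Lyz2 rose from 12.93 to 14.58 and Apoe from 5.81 to 9.04 in Evi1-WT.

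Hypoxia genes higher in vector than in untransduced cells did not come from scaling, with a median of 1.70 after quantile normalization. Nor did untransduced replicate 3 alone produce them, with 2.03 without that library. An effect found with the empty vector only, and not with the Evi1 constructs, does not match the medians against untransduced cells. These were 1.52 in Evi1-WT and 1.81 in Evi1-S436A. The medians cannot separate an effect of viral transduction from one of handling, as all transduced cells had both. Apart from the 48 h given for all samples, culture density, oxygen and time in culture were not recorded in the labels and could differ between untransduced and transduced cells.

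The absence of called genes between the 2 Evi1 forms did not come from a spread widened by the untransduced libraries, as a fit of the 6 libraries alone also called 0 genes. Differences below the size that could be called may exist, as 74% of simulated log2 changes of 1 but 4% of changes of 0.5 were called. The simulated data used 1 spread per gene for all groups. They held 200 changed genes, so isolated changes of 1 could also be missed in the real data. The rule for that test was set after its values were seen.

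The 6 libraries of a comparison can be split 3 against 3 in only 10 ways, the real grouping included, too few for a test. Splits with as many genes as the real grouping, itself included, numbered 1 of 10 for vector against untransduced (2404, highest other 0), 1 for Evi1-WT against vector (211, highest other 0), 1 for Evi1-S436A against vector (241, highest other 0) and 10 for the 2 Evi1 forms (0, highest other 0). For lists, splits with a count as large, the real grouping again included, numbered 4 (12, highest other 14), 1 (14, highest other 13), 2 (9, highest other 11) and 10 (0, highest other 12). Of 100 regroupings of the 9 transduced libraries, 2 gave as many shared genes as the real 163, itself included (highest other 165). Only 3 of the 100 kept the 3 vector libraries together, with both of these among them, and the highest with the vector libraries apart was 0. With the vector libraries apart, their difference from the Evi1 libraries falls inside the groups and widens the spread. A low count was then to be expected, as in the splits above that mix unlike groups. The regroupings do not address whether the 2 forms agree.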
